A study of Mus musculus with 12 samples.

How the data were processed

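Bulk RNA-seq was done on 12 mouse prostate tumours, 3 in each of 4 groups. Per the labels, 100000 PTE-82 cells in 40 µl of PBS and Matrigel were injected into the prostate. Lupron was given at 0.6 mg per mouse on day 4, antibodies on days 9 and 14, and tumours were taken after perfusion on day 17. Whether the Lupron groups also received control IgG is not given in the sources used here, nor are batches of library preparation or sequencing. RNA was isolated with RNeasy Plus columns, for which the sample labels and the series description name different kit sizes, and libraries were made with the NuGen Ovation Mouse RNA-Seq kit. Per the submitters' processing notes, reads were split with bcl2fastq 2.20.0.422, trimmed with cutadapt 1.8.1 and counted with HTSeq 0.6.1 on genome build mm10. The aligner, the gene annotation and the strand setting are not given in the sources used here.

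The deposited table gives raw counts, whole numbers for 23479 gene symbols in 12 libraries, with no normalization by the authors. Total counts per library ran from 20584363 to 29965355, and RNA integrity numbers in the labels from 8.2 to 9.8. Every column matched a sample label. No pair among 66 pairs of libraries looked like a duplicate: the lowest chi-square per degree of freedom, over genes with at least 20 counts, was 38.0, where resequencing of 1 library would give about 1. Spearman correlations between libraries ran from 0.71 to 0.986, and the first principal component held 60.1% of the variance of log CPM, with IgG replicate 3 at its end.

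Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passing edgeR's filter on low counts for the 4 groups (15082) were scaled with TMM factors and fitted with 1 mean per group over all 12 libraries, with the robust quasi-likelihood fit. Each comparison used the quasi-likelihood F test, two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were each treatment against IgG, the combination against each single treatment, the averaged effects of the antibody and of Lupron (6 libraries against 6), and their interaction. Levels are CPM on TMM-scaled library sizes. For a gene without counts in a group, 3 counts over the group were taken as the limit, 0.0383, 0.0382, 0.0396 and 0.0409 CPM for IgG, anti-CSF1, Lupron and the combination; such limits cover counting error only. For a comparison of 3 tumours with 3, an exact permutation test cannot give a p under 0.1, so the model that shares its estimate of spread across genes was used.

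A total of 31 gene lists with 454 symbols were written from general knowledge: markers of macrophages, monocytes, neutrophils, dendritic cells, T cells, NK and cytotoxic cells, B and plasma cells, mast cells, endothelium, fibroblasts, smooth muscle, skeletal muscle, fat, red blood cells, luminal and basal epithelium, normal prostate secretion and seminal vesicle, and genes of MHC class II, androgen response, cholesterol synthesis, cholesterol uptake, storage and efflux, steroid hormone synthesis, proliferation, interferon response, inflammatory cytokines, colony-stimulating factors and receptors, hypoxia and glycolysis, matrix remodelling, immediate early and heat shock response, and nerve and neuroendocrine cells. Some genes sit on a pair of lists: Csf1r and Msr1 are also macrophage markers, and Ndrg1 is on the androgen and hypoxia lists. Of the symbols, 5 were matched by an older name and 9 were not in the table. Lists were tested with camera from limma 3.58.1 on the edgeR counts, with the preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists in each comparison. Camera compares a list with all other genes. Beside it stand camera with a correlation estimated per list, and fry, which tests whether the genes of a list move, on balance, one way. Members were also counted after adjustment over the list alone. A list's level in a library is the mean of log2(CPM + 1).

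Some genes that the rules here give are not reported here. Genes named were Csf1, Csf1r and Erg, and for each comparison up to 8 called genes with the highest and 8 with the lowest fold change and a mean of at least 1 CPM, without overlap between groups in comparisons of a pair of groups. Where fewer than 5 were called in a comparison, the 5 with the smallest p in each direction were named as not passing. For each list described, up to 4 members with the smallest p were named. Predicted genes and antigen receptor segments were left out. Pgr, Stc1 and the others given with an adjusted p above the threshold belong to these. Sbp, which falls outside the rule, was chosen after its values were seen.

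The comparisons, lists, rule for naming genes and the following alternatives were chosen before the data were examined: DESeq2's scaling factors (RLE) or upper-quartile factors in place of TMM, the DESeq2 1.42.0 Wald test, no filter on low counts, a stricter filter (1 CPM in 3 libraries), a fit to the compared groups only, the replicate number as a block, the RNA integrity number as a covariate, the non-robust fit, and each library left out in turn. A further 3 were chosen after seeing the data: IgG replicate 3 and Lupron replicate 2 both left out, a tissue covariate (the mean level of the luminal, basal and smooth muscle lists), and removal of the seminal vesicle genes before scaling. When a library is left out, the groups with fewer tumours are assumed to vary like the others.

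The pipeline was tested on simulated data with each gene's estimated spread and the depth of these libraries. Genes were drawn independently around a common mean, without a library that stands apart and without correlation between genes. The rates given here therefore need not hold for the real libraries. Shuffled splits of the antibody groups called up to 153 genes. The split with 153 differed from the real one only by an exchange of IgG replicate 3 and anti-CSF1 replicate 1, with the sides renamed. It is thus not free of the antibody's effect and gives no rate of false calls. Among genes changed 4-fold, edgeR recovered 44.1% for anti-CSF1 against IgG, 48.4% for the combination against Lupron, 76.3% for the averaged antibody effect and 8.96% for the interaction. Among unchanged genes it called from 0 to 7 of 14689 to 14712, and DESeq2 up to 59. Gene coordinates come from GENCODE M21. No library was left out of the comparisons.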

Results

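RNA was measured in bulk from mouse prostate tumours grown in the prostates of C57BL/6J mice from PTE-82 cells, a mouse prostate cancer line that carries the TMPRSS2-ERG fusion. The 12 tumours fell into 4 groups of 3: control IgG, an antibody against the macrophage growth factor CSF1 (anti-CSF1), Lupron, which lowers testosterone by acting on the pituitary, and Lupron with anti-CSF1. The deposited table held raw counts for 23479 gene symbols, and the total per library lay between 20584363 and 29965355 counts. Gene levels are given as CPM, read counts relative to the scaled library total, as mean ± SD with n = 3 tumours per group, and changes as log2 fold changes ± standard error. Of the symbols, 15082 had enough counts to be tested.

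The libraries differed in their levels of genes typical of non-tumour tissue. IgG replicate 3 had the highest level of 12 libraries for 6 lists of non-tumour tissue: luminal epithelium, basal epithelium, normal prostate secretion, smooth muscle, skeletal muscle and fat. It was lowest for fibroblast (6.12) and endothelial genes (4.07) and ranked 11 of 12 for seminal vesicle genes. Its smooth muscle level was 9.37 (mean log2 of CPM plus 1), against 4.32 to 7.50 in the other libraries, and its luminal level was 7.50, against 2.54 to 5.12. Its level of proliferation genes was 2.74, against 5.94 to 6.89 elsewhere. The prostate secretory gene Sbp alone took 4.82% of its counts. Genes of the seminal vesicle took 29.3% of the counts of Lupron replicate 2, 10.5% of those of IgG replicate 2, 10.2% of anti-CSF1 replicate 1, 7.73% of the combination's replicate 3, and from 0.028% to 5.12% in the other 8 libraries. The biological coefficient of variation over the 12 libraries was 0.471, and 0.376 without IgG replicate 3. Each comparison was also fitted without that library, as planned for every library. IgG replicate 2 was next highest for each of the 6 lists of non-tumour tissue, at 7.50 for smooth muscle and 5.12 for luminal genes. A fit without IgG replicate 3 therefore still has a library high in these lists in its IgG group.

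**Figure D1:**
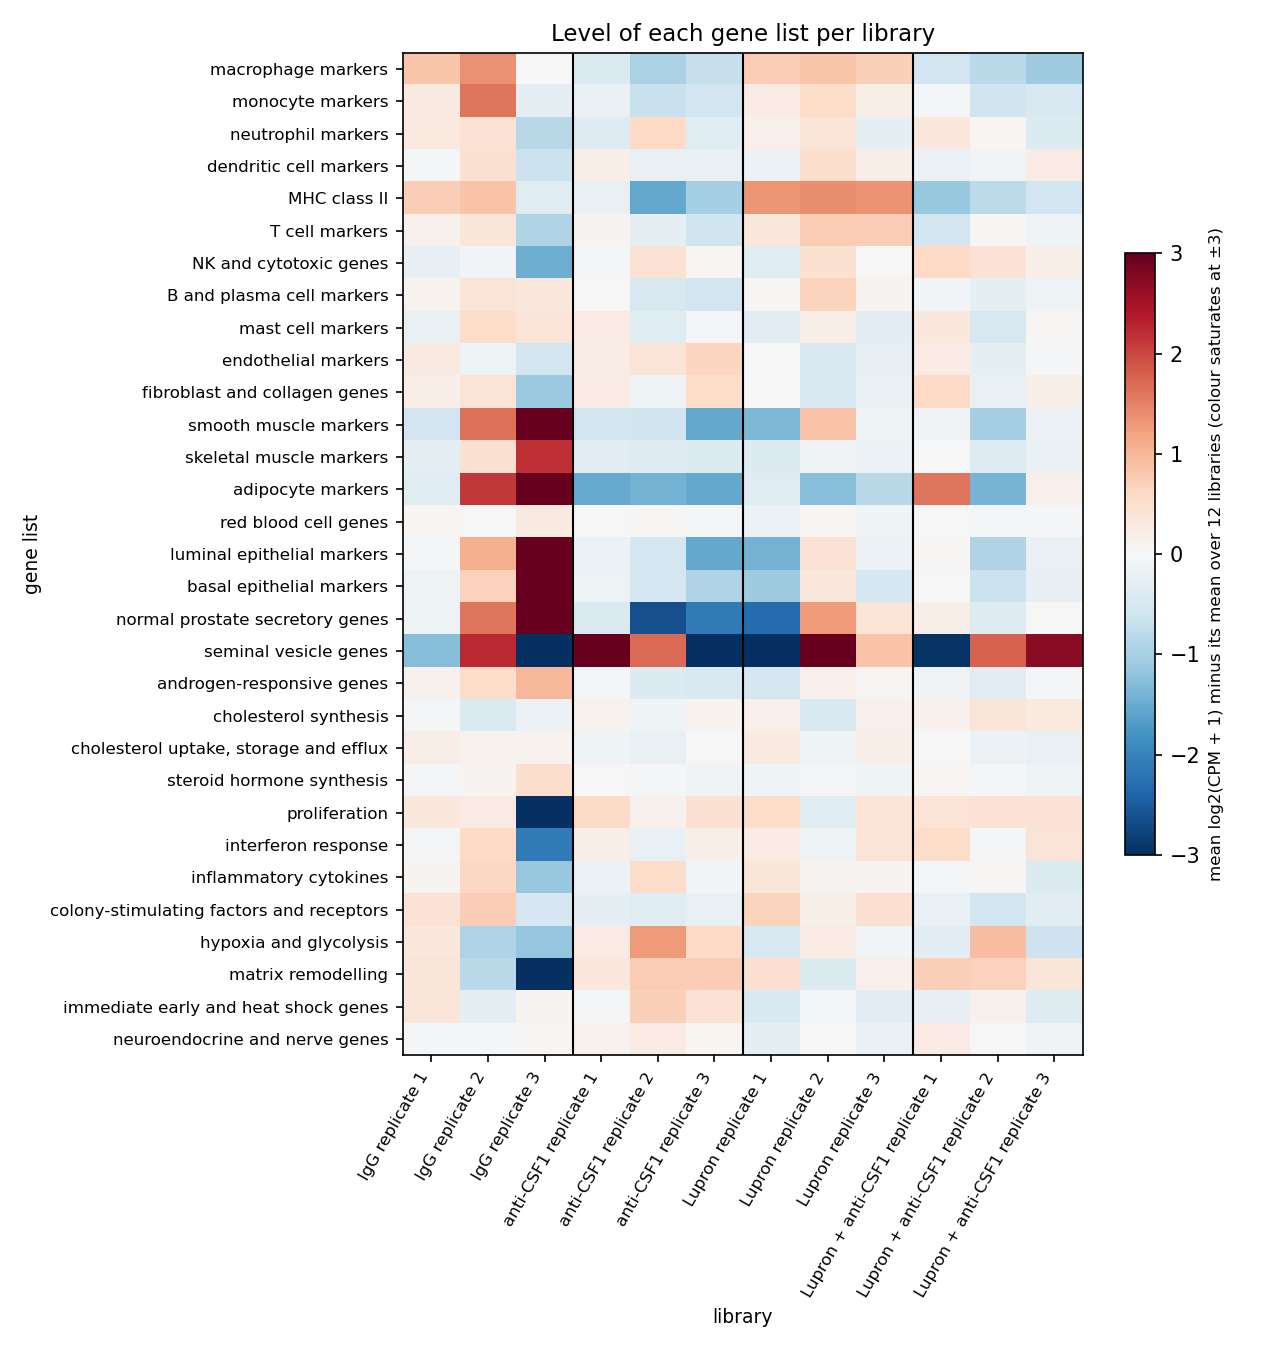
Heat map of gene list levels in the 12 libraries (columns) for the lists (rows); colour gives the list's mean log2(CPM + 1) minus its mean over the 12 libraries. IgG replicate 3 is highest for 6 lists of non-tumour tissue (luminal, basal, secretory, smooth muscle, skeletal muscle and fat). It is lowest for proliferation, at 2.74 before centring, and also for fibroblast and endothelial genes.

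The effect of the antibody averaged over tumours with and without Lupron answers what blocking CSF1 did to the tumours. Macrophage genes fell. CSF1 keeps macrophages alive, and they express its receptor gene, Csf1r. Csf1r fell 5.22-fold (log2 −2.38 ± 0.31, adjusted p = 0.00798). Bulk RNA cannot tell a loss of macrophages from lower expression in each of them. Csf1r had 104 ± 48.6 CPM with IgG, 21.1 ± 8.89 with anti-CSF1, 108 ± 29.3 with Lupron and 19.6 ± 4.47 with both, and all 6 tumours with the antibody lay below all 6 without it. Lists of genes were tested with camera, a test of a list against all other genes. Of the 28 macrophage genes tested, 28 had a negative estimate, with a median of −2.09 (−2.06 with genes absent from a group set to the counting limit), and 18 passed the test over all genes, 21 when adjusted over the list alone. Among them, Mrc1 (−1.92 ± 0.25) and the complement gene C1qb (−2.46 ± 0.32) fell in every one of 12 fits that left out a library. Fcna, a ficolin gene outside the list, fell 15.7-fold (−3.98 ± 0.37, adjusted p = 0.00306). Cd209f fell from 12.2 ± 10.0 CPM with IgG and 1.83 ± 1.23 with Lupron to no counts with anti-CSF1 and 2 counts with the combination (adjusted p = 0.00959). The ligand gene itself, Csf1, had a log2 change of −0.23 ± 0.33 (adjusted p = 0.702). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 282 genes passed, 12 higher and 270 lower, and DESeq2 called 1425, which included these 282. Of the 282, 175 had no overlap between the 6 tumours with and the 6 without the antibody. Among all tested genes 361 had no overlap, where chance gives 0.216%. The count ran from 65 without anti-CSF1 replicate 3 to 1577 without IgG replicate 1; it was 476 without IgG replicate 3, 279 of them shared, 152 without IgG replicate 2, 83 without anti-CSF1 replicate 2, 110 and 135 without Lupron replicates 2 and 3, and 158, 84 and 90 without the combination's replicates 1, 2 and 3.

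**Figure D2:**
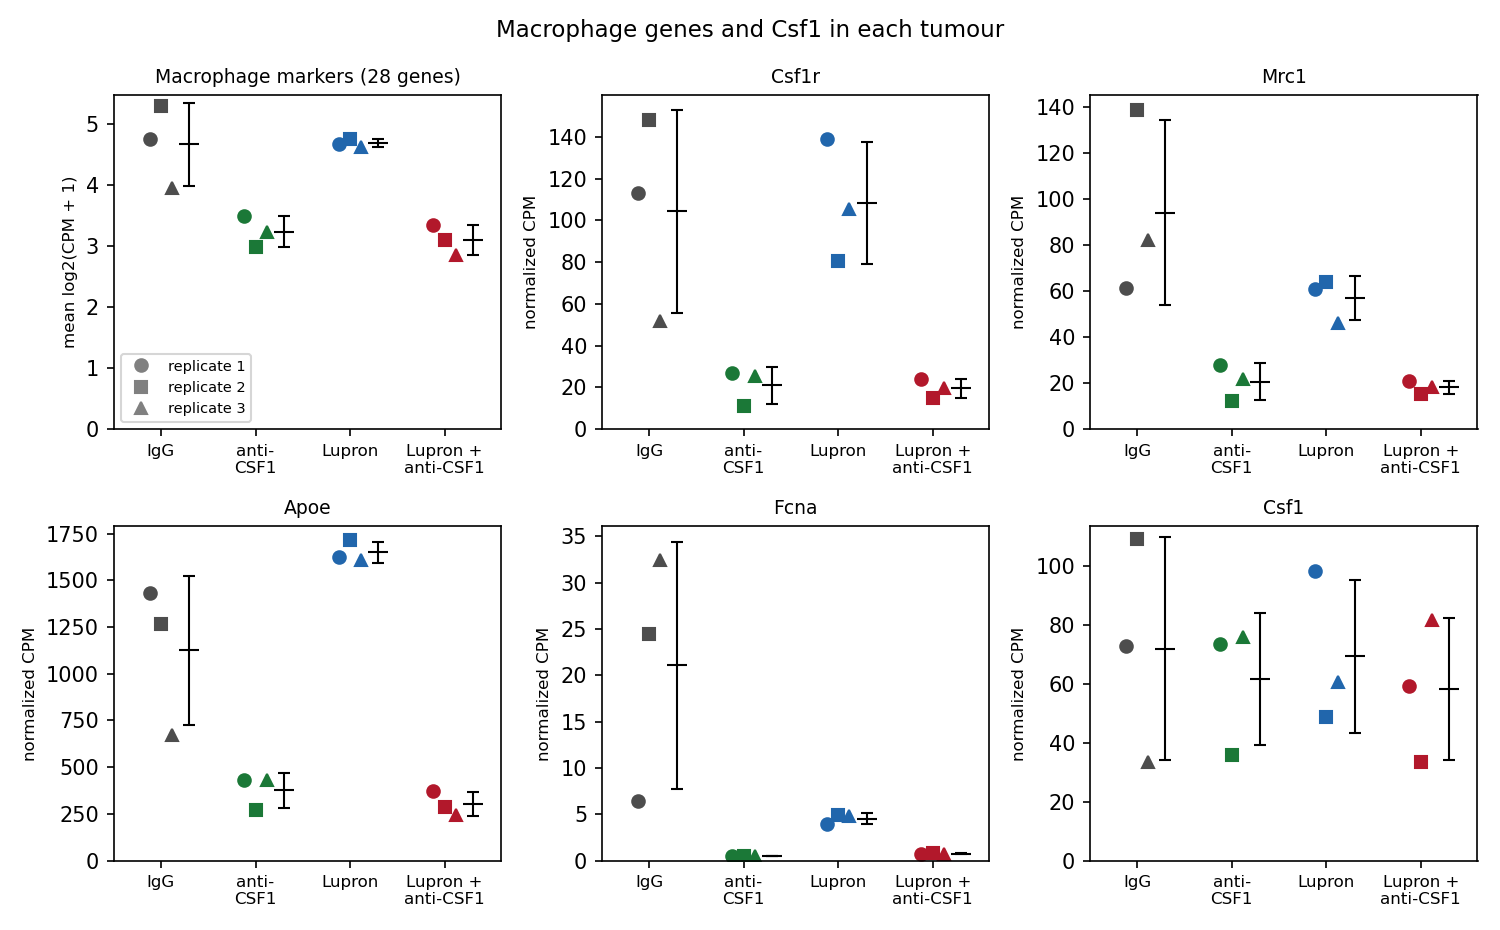
Level of the macrophage list (mean log2(CPM + 1)) and of Csf1r, Mrc1, Apoe, Fcna and Csf1 (CPM) in each tumour by group; points are tumours, marker shape gives the replicate number, and bars are mean ± SD (n = 3). The list stands at 4.67 ± 0.68 with IgG and 3.23 ± 0.25 with anti-CSF1, and at 4.69 ± 0.06 with Lupron and 3.10 ± 0.24 with the combination.

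Genes of antigen presentation fell with the macrophage genes, and so did Cd4 and Cd22. MHC class II genes, which macrophages, dendritic cells and B cells use to present peptides, had a median of −2.15, and 7 of 9 passed over all genes and over the list alone, among them H2-DMb1 (−2.52 ± 0.27, adjusted p = 0.0053) and H2-Ab1 (−2.22 ± 0.32, adjusted p = 0.00861). H2-Ab1 had 254 ± 125 CPM with IgG, 75.4 ± 39.7 with anti-CSF1, 532 ± 31.1 with Lupron and 82.6 ± 18.0 with both. In the T cell list, Cd4, which mouse macrophages can also carry in some tissues, fell (−2.05 ± 0.28, adjusted p = 0.00798) as 1 of 19 genes. The other members had values such as −0.91 ± 0.36 for Cd3e (adjusted p = 0.215), and the median was −0.75. In the B cell list Cd22 fell (−2.47 ± 0.36, adjusted p = 0.00861) as 1 of 9, and 3 passed when adjusted over the list alone. The receptor gene Csf2ra (−1.47 ± 0.14, adjusted p = 0.00306) fell beside Csf1r in the list of colony-stimulating factors, whose median was −0.81. Cd4, Cd22, Csf2ra and the 4 MHC genes with the smallest p passed in every fit that left out a library. In the monocyte list F13a1 fell (−1.80 ± 0.35, adjusted p = 0.0268) as 1 of 9, but it passed in 4 of the 12 fits that left out a library, those without IgG replicate 1 or 3, Lupron replicate 3 or the combination's replicate 1. The lists of neutrophil (median −0.44, camera adjusted p = 0.805), dendritic cell (−0.32, 0.492) and mast cell (−0.17, 0.472) markers were not called.

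The granzyme genes Gzmc to Gzmg rose with the antibody, while Gzmb and Gzma (0.47 ± 0.58, adjusted p = 0.658) did not pass over all genes. Granzymes are proteases that cytotoxic lymphocytes release. Gzmc rose 10.5-fold (3.40 ± 0.70, adjusted p = 0.0364), from 13.8 ± 16.3 CPM with IgG to 153 ± 70.0 with anti-CSF1, and stood at 19.7 ± 4.22 with Lupron and 197 ± 102 with both. Gzmd rose by 6.73 ± 1.10 (adjusted p = 0.0132), with 82 and 43 counts in all over the IgG and Lupron groups against 5818 and 6380 in the antibody groups. Gzme, Gzmf and Gzmg rose by 6.19 ± 1.24, 6.84 ± 1.33 and 8.32 ± 1.34 (adjusted p = 0.0322, 0.0283 and 0.013), from under 1 CPM in both groups without antibody. These genes lie side by side on chromosome 14, and the ratios among Gzmd, Gzme, Gzmf and Gzmg counts moved by factors of 1.49 to 2.89 between the antibody libraries, while Gzmd over Gzmc ran from 0.0913 to 0.909. All 6 antibody tumours lay above all 6 others for Gzmc, Gzmd, Gzmf and Gzmg, and 5 of 6 for Gzme. Their calls differ in how they hold when a library is left out. Gzmg lost its call without Lupron replicate 2 (adjusted p = 0.0596) and Gzmd without Lupron replicates 2 and 3 (0.0579 and 0.057). Gzmc kept its call only without IgG replicates 1 or 3 or anti-CSF1 replicate 1, Gzmf only without IgG replicate 1 or anti-CSF1 replicate 1, and Gzme only without those or Lupron replicate 2; over the 12 fits Gzmc stayed between 3.11 and 4.18. Gzmb and Gzma are both in the list of natural killer (NK) and cytotoxic genes. Gzmb had 9.41 ± 7.85, 32.5 ± 11.4, 13.8 ± 3.94 and 45.0 ± 13.9 CPM in the order of groups above (1.75 ± 0.51, adjusted p = 0.123). It passed without IgG replicate 1 (0.0371) and without IgG replicate 3 (0.00627). When adjusted over the list alone, Eomes, Ncr1, Gzmb and Prf1 passed, the list's median was 0.43, and its camera call (adjusted p = 0.00531) held neither with an estimated correlation (0.509) nor without IgG replicate 3, where the median was 0.24 (0.051).

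Il33, an alarm cytokine of stromal and epithelial cells, rose 3.30-fold (1.72 ± 0.28, adjusted p = 0.0132) and passed in every fit that left out a library, with 86.8 ± 36.6 CPM with IgG, 368 ± 160 with anti-CSF1, 114 ± 12.5 with Lupron and 292 ± 123 with both. The neuropeptide genes Scg2 (2.99 ± 0.57, adjusted p = 0.0253) and Npy (2.52 ± 0.52, 0.0364) rose too, each passing in 4 of the 12 fits, those without IgG replicate 1 or 3, anti-CSF1 replicate 1 or Lupron replicate 1. Scg2 was the 1 called member of the list of neuroendocrine genes, whose median was 0.16 (camera adjusted p = 0.427).

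**Figure D3:**
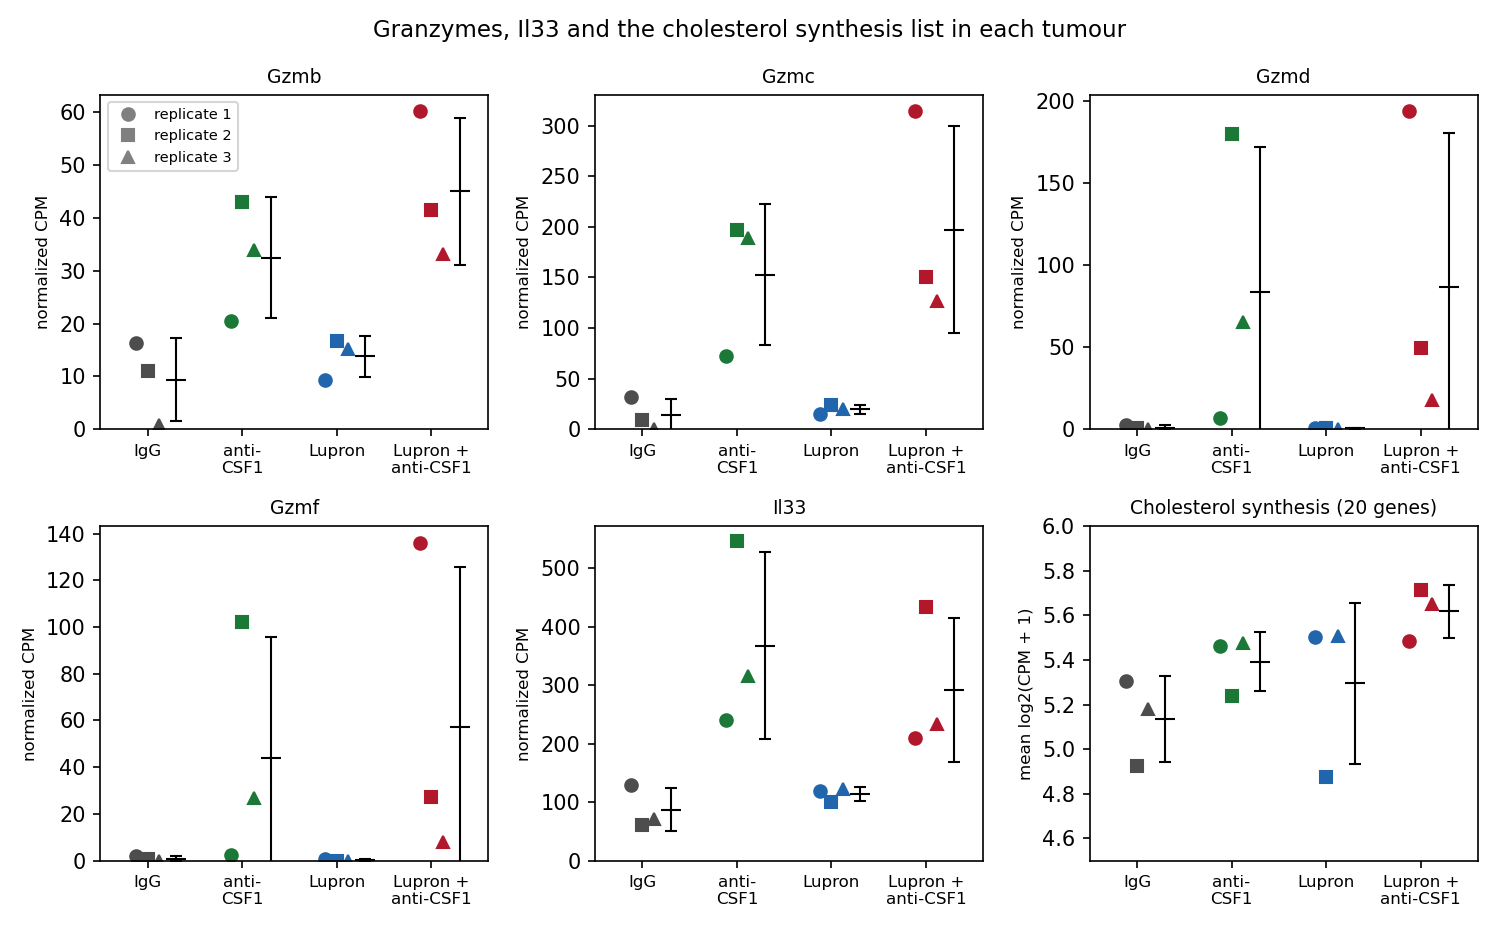
CPM of Gzmb, Gzmc, Gzmd, Gzmf and Il33 and level of the cholesterol synthesis list (mean log2(CPM + 1)) in each tumour by group; points are tumours, marker shape gives the replicate number, and bars are mean ± SD (n = 3). Gzmd is low without the antibody (1.06 and 0.622 CPM) and spread widely with it (83.8 ± 87.9 and 86.8 ± 93.7 CPM).

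Of the genes that handle cholesterol in macrophages, 4 fell with the antibody, and genes that make cholesterol stood slightly higher. Apoe, a carrier of cholesterol that macrophages secrete, fell 4.04-fold (−2.02 ± 0.23, adjusted p = 0.0055) in all 12 fits that left out a library, from 1124 ± 398 to 376 ± 93.4 CPM without Lupron and from 1650 ± 56.8 to 302 ± 65.7 with it. The sterol sensor Nr1h3 (−1.50 ± 0.25, adjusted p = 0.0155), the export pump Abca1 (−1.08 ± 0.20, 0.0203) and the scavenger receptor Msr1 (−2.12 ± 0.47, 0.0488) fell too. They passed in 8, 6 and 2 of the 12 fits: removal of anti-CSF1 replicate 2 or 3, Lupron replicate 2 or the combination's replicate 2 ended all 3 calls, removal of Lupron replicate 3 or the combination's replicate 3 also that of Abca1, and Msr1 passed only without IgG replicate 1 or 3. Over the 21 genes of uptake, storage and efflux, 11 had positive and 10 negative estimates, the median was 0.09, and camera gave an adjusted p of 0.183, but called the list lower without IgG replicate 3 (0.03, and 0.492 with an estimated correlation), where the median was 0.10. Of the 20 genes of cholesterol synthesis, 16 had positive estimates with a median of 0.29 (camera adjusted p = 0.000759, and 0.46 with an estimated correlation), and 0 passed singly, over all genes or the list alone. The steroid hormone synthesis list had a median of −0.64 (0.805), and of −0.098 without IgG replicate 3.

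Lists of non-tumour tissue were called lower with the antibody, in the direction that their excess in IgG replicate 3 gives, and had adjusted p from 0.46 to 0.509 with an estimated correlation. The medians were −1.54 for luminal, −1.55 for basal, −3.12 for secretory, −2.23 for smooth muscle, −1.56 for skeletal muscle and −4.66 for fat genes (−3.19 with absent genes set to the counting limit). Leaving out IgG replicate 3 gave −0.80 (−0.76 at the limit), −0.38, −1.97, −1.50, −0.59 and −3.06 (−2.13 at the limit). Members included Spint1 (−2.03 ± 0.46, adjusted p = 0.0545), Myh11 (−2.66 ± 0.79, 0.126) and Pigr (−3.26 ± 0.91, 0.108), and 0 of these 6 lists' genes passed over all genes. Adjusted over the list alone, 9 smooth muscle, 4 secretory, 3 skeletal muscle, 2 luminal and 2 fat genes passed. The luminal, secretory, smooth muscle and fat lists kept their camera calls in all 12 fits that left out a library, and without IgG replicate 3 skeletal muscle and basal genes did not. The proliferation list had 26 of 26 positive estimates and a median of 0.41, the interferon list a median of 0.20, the hypoxia list 0.89, matrix remodelling 0.94, endothelial genes 0.41 and fibroblast genes 0.47, with adjusted p from 0.46 to 0.748 with an estimated correlation. These 6 medians were 0.16, 0.031, 0.69, 0.67, 0.33 and 0.24 without IgG replicate 3. In the hypoxia list Pfkfb4 went against the rest and fell (−1.39 ± 0.27, adjusted p = 0.0296), passing in 3 of 12 fits, those without IgG replicate 1 or 3 or Lupron replicate 1. In the list of androgen-responsive genes (median −0.20, camera adjusted p = 0.102), Maf (−0.83 ± 0.18, adjusted p = 0.0452) and Tmprss2 (−3.16 ± 0.69, 0.0452) fell, and each passed in 2 of 12 fits, Maf without IgG replicate 1 or 3 and Tmprss2 without IgG replicate 1 or Lupron replicate 1. Inflammatory cytokines (median −0.44, 0.997), seminal vesicle genes (0.52, 0.571), immediate early genes (0.32, 0.172) and the 1 red blood cell gene tested (−0.40, 0.881) were not called. With IgG replicate 3 left out, inflammatory cytokines were called lower (−0.57, 0.0417, and 0.492 with an estimated correlation), the seminal vesicle median was 0.24 and the red blood cell gene stood at −0.071.

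For the antibody averaged over Lupron, the set test with a preset correlation called 20 of 31 lists, 8 up and 12 down, and with an estimated correlation 1, the macrophage list (adjusted p = 0.043). The self-contained test fry called 4: macrophage, MHC class II, B cell and colony-stimulating factor genes. The other lists had estimated-correlation values from 0.109 for MHC class II upward. Without IgG replicate 3, 15 of the 20 were still called and 3 lists passed with an estimated correlation: macrophage (0.00831), MHC class II (0.0223) and colony-stimulating factors (0.0251). The calls of T cell genes ended without IgG replicate 1, those of NK and skeletal muscle genes without IgG replicate 3, and those of fibroblast, basal and interferon genes held in 5 of 12 fits. Fibroblast genes, with medians from 0.24 to 0.65, were called without IgG replicate 2, anti-CSF1 replicate 2, Lupron replicate 1 or the combination's replicate 2 or 3. Basal genes, from −1.89 to −0.38, were called without IgG replicate 1 or 2, anti-CSF1 replicate 1, or Lupron replicate 1 or 3. Interferon genes, from 0.031 to 0.41, were called without IgG replicate 2, anti-CSF1 replicate 2, Lupron replicate 1 or 3, or the combination's replicate 2.

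**Figure D4:**
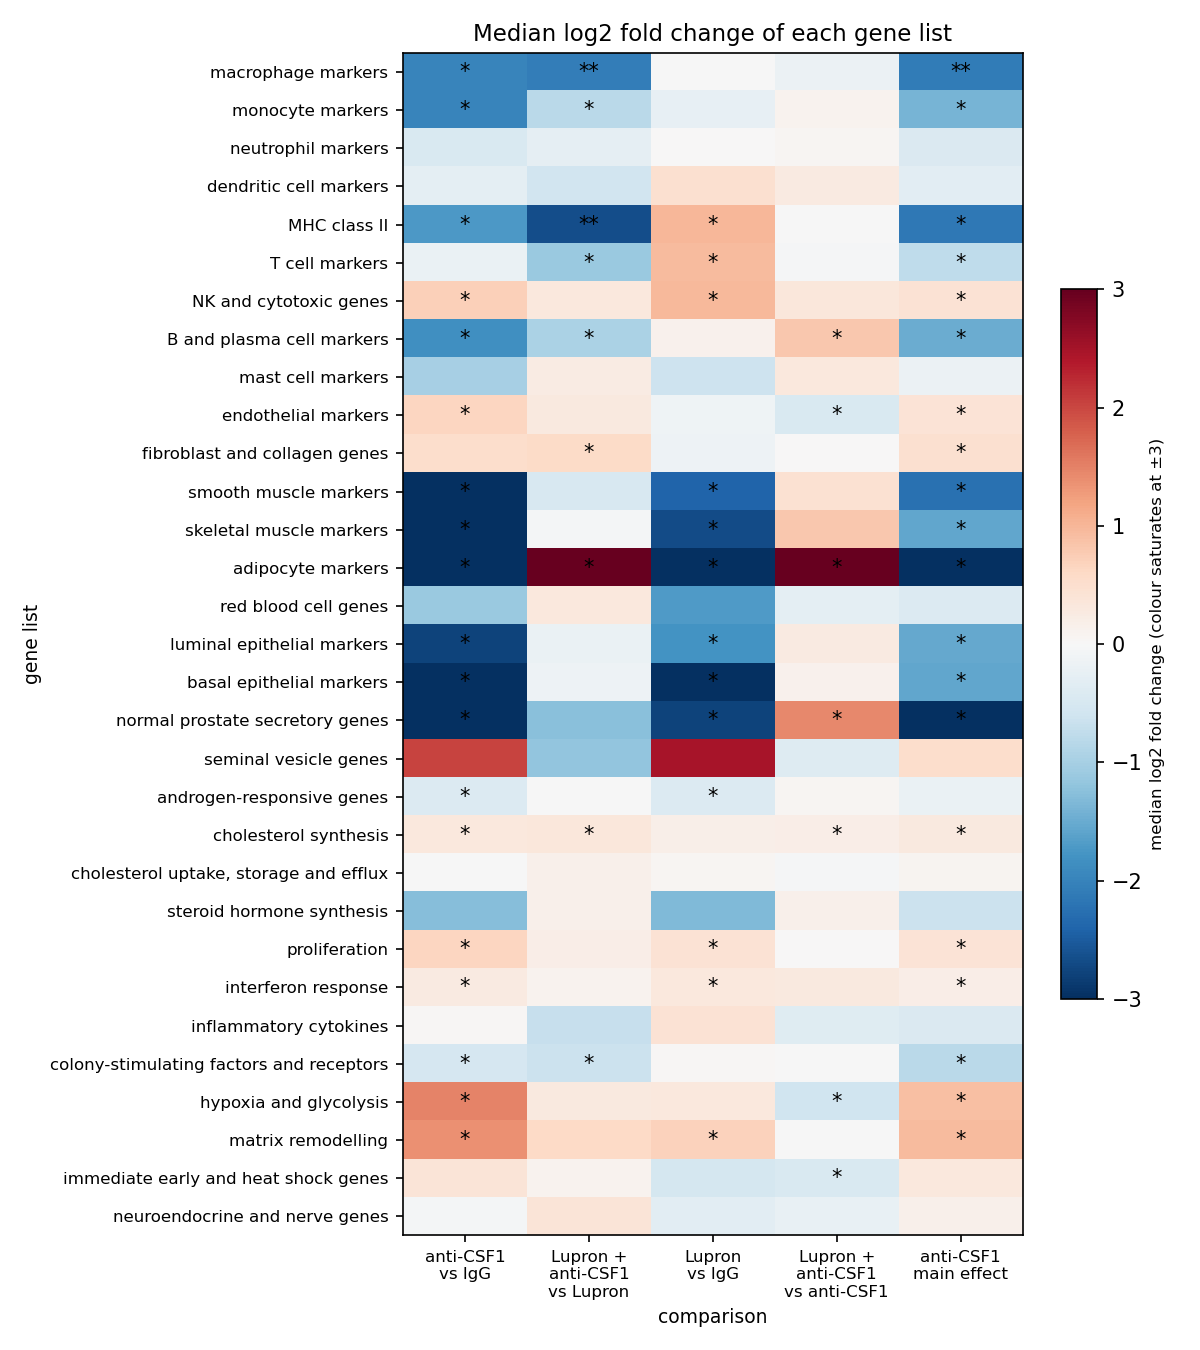
Median log2 fold change of each gene list (rows) in 4 comparisons of groups and for the antibody averaged over Lupron (columns); colour saturates at ± 3, 1 star marks a list called by the set test with preset correlation and 2 stars one also called with an estimated correlation. The macrophage list stands at −1.98 and −2.08 for the antibody without and with Lupron and at −0.02 for Lupron alone.

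Anti-CSF1 against IgG asks what the antibody did on its own, in 3 tumours against 3. The macrophage list had a median of −1.98 with 28 of 28 estimates negative. No member passed over all genes, 20 passed when adjusted over the list alone, and the camera call (adjusted p = 3.88e-15) had an adjusted p of 0.413 with an estimated correlation. Csf1r was at −2.30 ± 0.43 (adjusted p = 0.0875). Fcna fell 41.0-fold, from 21.1 ± 13.3 to 0.510 ± 0.0118 CPM (−5.36 ± 0.56, adjusted p = 0.0153), and it was the 1 gene called by edgeR, with 3446 at an unadjusted p under 0.05 and 1841 called by DESeq2. Its call held in 6 of 12 fits that left out a library. Without IgG replicate 3, 168 genes passed, all lower, among them 15 macrophage genes with Csf1r (adjusted p = 0.00689) as 1 of them, and the macrophage list, with a median of −2.35, held with an estimated correlation (0.0328). Without IgG replicate 1, which leaves the 2 IgG libraries highest for the 6 lists of non-tumour tissue, 2611 passed. Without IgG replicate 2, Lupron replicate 2 or 3, or any single anti-CSF1 library, 0 passed.

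Other lists in that comparison were called with the preset correlation but not with an estimated one, and fry called the macrophage and B cell lists (adjusted p = 0.043 each). MHC class II genes (median −1.71, 7 of 9 passing over the list alone), B cell genes (−1.84, 5 of 9), monocyte genes (−1.98, 5 of 9) and colony-stimulating factors (−0.51, 2 of 8) were lower. NK genes (0.73), endothelial genes (0.64), proliferation (0.64), hypoxia (1.48), matrix remodelling (1.38), interferon (0.26) and cholesterol synthesis (0.31) were higher. The non-tumour tissue lists had medians from −2.77 for luminal to −4.72 for secretory genes, and −9.91 for fat genes with absent genes set to the counting limit. Androgen-responsive genes were called lower, with a median of −0.41 and 6 of 20 passing over the list alone, among them Tmprss2, at 108 ± 116 CPM with IgG and 3.77 ± 1.08 with anti-CSF1. Genes of cholesterol uptake, storage and efflux split, with a median of −0.01, and 1 higher and 4 lower when adjusted over the list alone, Abca1 (−1.42 ± 0.28) and Apoe (−1.58 ± 0.32) among the lower. In the list of steroid hormone synthesis the median was −1.27 (camera adjusted p = 0.297), and −0.41 without IgG replicate 3. Removing IgG replicate 3 ended the calls of NK, skeletal muscle, basal, proliferation and interferon genes, and the proliferation median was then 0.099. Without that library the medians were 0.29 for NK, 0.40 for endothelial, 0.84 for matrix, −0.16 for interferon, −0.19 for androgen-responsive, −0.91 for colony-stimulating factor, −1.39 for luminal, −1.06 for basal, −2.05 for smooth muscle, −2.20 for skeletal muscle and −3.66 for secretory genes, and −7.39 for fat genes at the counting limit, and T cell genes were called lower (−0.66 in place of −0.21, adjusted p = 0.00224, and 0.468 with an estimated correlation). Those of monocyte, basal, androgen-responsive, cholesterol synthesis, interferon and colony-stimulating factor genes each also ended without some anti-CSF1 or IgG library: monocyte genes without IgG replicate 2 or anti-CSF1 replicate 2, basal genes without anti-CSF1 replicate 3, androgen-responsive genes without anti-CSF1 replicate 2, cholesterol synthesis without IgG replicate 2 or anti-CSF1 replicate 1 or 3, interferon without anti-CSF1 replicate 1 or 3, and colony-stimulating factors without IgG replicate 1 or 2 or anti-CSF1 replicate 1 or 2.

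Lupron with anti-CSF1 against Lupron asks what the antibody adds to Lupron. The macrophage list had a median of −2.08 (−1.98 with absent genes at the counting limit), 25 of 28 estimates negative and 19 passing when adjusted over the list alone, and this call held with an estimated correlation (adjusted p = 0.0111). Csf1r was at −2.46 ± 0.44 (adjusted p = 0.0755) and Apoe at −2.45 ± 0.33 (0.058). MHC class II genes had a median of −2.67 with 9 of 9 negative, 7 passing over the list alone, and the call held with an estimated correlation (0.0131). H2-DMb1 was at −3.06 ± 0.40 (adjusted p = 0.058). T cell genes had 19 of 19 negative estimates and a median of −1.12, such as Cd4 (−2.61 ± 0.41, adjusted p = 0.058) and Cd3e (−1.37 ± 0.52, 0.797), with an adjusted p of 0.473 with an estimated correlation. No gene passed over all genes in edgeR, where the lowest adjusted p was 0.058, 642 had an unadjusted p under 0.05, and DESeq2 called 235. The IgG libraries are in neither group here but share in the filter, the scaling and the estimate of spread, whose parts were not separated: without IgG replicate 3, 210 genes passed, 208 of them lower, among them 15 macrophage genes with Csf1r (adjusted p = 0.00436) as 1 of them. With the 2 groups fitted alone, 204 passed, 200 of them lower, and without IgG replicates 1 and 2 the counts were 1 and 13.

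Cholesterol synthesis was called higher in the combination than with Lupron alone with the preset correlation only. The list had 18 of 20 positive estimates and a median of 0.33 (camera adjusted p = 8.88e-05, and 0.583 with an estimated correlation), and 0 genes passed singly. Idi1 stood at 23.4 ± 1.94 CPM with Lupron and 35.2 ± 10.1 with the combination (0.59 ± 0.24, adjusted p = 0.914). Without Lupron replicate 2 the median was 0.19 and the list was not called (adjusted p = 0.073). Fibroblast genes (median 0.58) and fat genes (3.12) were called higher, both calls ending with an estimated correlation (0.683 and 0.698) and without Lupron replicate 2 or the combination's replicate 1. B cell genes (−0.95, of which Cd22 passed over the list alone), monocyte genes (−0.81) and colony-stimulating factors (−0.65) were called lower, with adjusted p from 0.134 to 0.488 with an estimated correlation, and the last of these held with it without IgG replicate 3 (0.0177). Uptake, storage and efflux genes had a median of 0.16 (adjusted p = 0.0854), with Apoe among 3 lower over the list alone. This list was called lower without IgG replicate 3 (0.0193), as were inflammatory cytokines (0.0106), while proliferation (0.0159) and matrix genes (0.00577) were called higher, with adjusted p from 0.476 to 0.733 with an estimated correlation. Androgen-responsive (camera adjusted p = 0.903) and steroid synthesis genes (median 0.16, 0.324) were not called.

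Lupron against IgG asks what Lupron did to the tumours. No testosterone values were among the data used here, so how far Lupron lowered androgens was not tested. The level of seminal vesicle genes (mean log2 of CPM plus 1) was 8.16 ± 3.17 with IgG and 9.79 ± 3.90 with Lupron. No gene passed in edgeR: the lowest adjusted p was 0.284, 2478 genes had an unadjusted p under 0.05, and DESeq2 called 404, 26 higher and 378 lower. That 2478 was reached by 2 of 10 splits of these libraries, the real one included (highest other 3969). Erg stood at 12.0 ± 4.19 CPM with IgG and 14.7 ± 3.48 with Lupron. Which cells carried these Erg counts, and whether they came from the fusion, was not tested. Androgen-responsive genes had 17 of 20 negative estimates, a median of −0.41 (camera adjusted p = 0.0154, and 0.52 with an estimated correlation) and 0 genes passing, over all genes or the list alone. Steap4 was the member with the smallest p (−3.49 ± 0.96), at 34.4 ± 38.9 and 3.07 ± 1.35 CPM, and the list's call ended without Lupron replicate 1 (adjusted p = 0.0636), while without IgG replicate 3 the median was −0.22 (0.0325). The genes with the smallest p were Cav1, at 225 ± 90.2 and 82.3 ± 13.5 CPM (−1.45 ± 0.30, adjusted p = 0.284), and Sfrp1 (−2.36 ± 0.50) among the lower, and Serpinb6b (1.15 ± 0.26) and Tmem18 (0.88 ± 0.21) among the higher. Without IgG replicate 1, 653 genes passed, 495 of them lower, and without each of the other 11 libraries 0 passed. The IgG group without replicate 1 holds the 2 libraries highest for the 6 lists of non-tumour tissue. Whether this gave the 653 genes was not tested.

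Lists of antigen presentation, T cells and NK cells stood higher in Lupron tumours than with IgG. The macrophage list had a median of −0.02 with 14 of 28 estimates on each side (adjusted p = 0.895), and without IgG replicate 3 it was called lower with a median of −0.30 (adjusted p = 0.0463, and 0.684 with an estimated correlation). MHC class II genes had 9 of 9 positive estimates and a median of 1.00, such as H2-Aa, at 171 ± 72.1 and 367 ± 19.0 CPM. T cell genes had 18 of 19 positive and a median of 0.95, such as Cd3g, at 4.03 ± 2.72 and 12.5 ± 5.55 CPM. NK genes had a median of 0.97. The MHC class II, T cell and NK lists were called with the preset correlation and had adjusted p from 0.52 to 0.583 with an estimated correlation, and 0 of their genes passed. Their medians were 0.65, 0.47 and 0.53 without IgG replicate 3, where the NK list was not called (0.202). Lists of luminal (−1.79, 9 passing over the list alone), basal (−3.49, 6), smooth muscle (−2.40, 6), skeletal muscle (−2.68), secretory (−2.78) and fat genes (−6.20, 7) were called lower in Lupron tumours with the preset correlation, with adjusted p from 0.52 to 0.583 with an estimated one, and these 6 are among the 9 lists whose level was highest in IgG replicate 3, the others being androgen-responsive, steroid synthesis and red blood cell genes. Without that library their medians were −0.80, −0.67, −0.92, −1.40, −0.87 and −3.56, and skeletal muscle was not called. Proliferation (0.44), interferon (0.31) and matrix remodelling (0.70) were called higher, but not with an estimated correlation (0.732, 0.75 and 0.699) or without IgG replicate 3 (medians −0.11, −0.14 and 0.23). The basal and secretory calls ended without Lupron replicate 1. Cholesterol synthesis (median 0.17, adjusted p = 0.126), uptake and efflux (0.05, 0.776) and steroid synthesis (−1.33, 0.0666) were not called. Removal of IgG replicate 3 took the steroid median to −0.30 and that of uptake and efflux to −0.042. It added calls of cholesterol synthesis as higher (0.22, adjusted p = 0.0189) and of monocyte (−0.78, 0.0231), endothelial (−0.38, 0.0231) and fibroblast genes (−0.51, 0.0119) as lower, with adjusted p from 0.601 to 0.684 with an estimated correlation.

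Lupron with anti-CSF1 against anti-CSF1 asks what Lupron adds in tumours given the antibody. No gene passed in edgeR, with 294 at an unadjusted p under 0.05 and 6 called by DESeq2, and 0 passed in any fit that left out a library. The progesterone receptor gene Pgr stood at 4.22 ± 1.80 CPM with anti-CSF1 and 0.317 ± 0.0751 with both (−3.71 ± 0.77, adjusted p = 1), Stc1 at 22.9 ± 2.94 and 10.2 ± 2.14 (−1.17 ± 0.29), and Kit at 9.90 ± 1.03 and 4.89 ± 0.697 (−1.02 ± 0.26). Macrophage genes had a median of −0.17 (camera adjusted p = 0.0959) and androgen-responsive genes one of 0.06 (0.513). Cholesterol synthesis had 19 of 20 positive estimates and a median of 0.20 (0.00208, and 0.933 with an estimated correlation), a call that ended without anti-CSF1 replicate 2 or the combination's replicate 2. Endothelial genes (−0.45, 13 of 14 negative), hypoxia genes (−0.61, 18 of 19) and immediate early genes (−0.45, 11 of 12) were called lower. Fat genes (6.54 with absent genes at the counting limit), secretory genes (1.45) and B cell genes (0.81) were called higher, and 0 of these lists held with an estimated correlation. Interferon genes (0.29) were called higher without IgG replicate 3 (0.00177, and 0.829 with an estimated correlation). The call of B cell genes ended without IgG replicate 3, anti-CSF1 replicate 2 or 3, Lupron replicate 2, or the combination's replicate 1 or 3, with medians from 0.11 to 2.07 over the fits.

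The combination against IgG asks what both treatments did together. The macrophage list had a median of −2.21 with 27 of 28 negative and 24 passing when adjusted over the list alone (camera adjusted p = 5.93e-18, and 0.296 with an estimated correlation). Fcna fell to 0.750 ± 0.0997 CPM (−4.81 ± 0.54, adjusted p = 0.0334) and was the 1 gene called by edgeR, with 3922 at an unadjusted p under 0.05 and 2076 called by DESeq2. The call of Fcna held in 2 of 12 fits, without IgG replicate 1 (2213 genes passed) and without IgG replicate 3 (208 passed, 194 of them lower, 15 macrophage genes among them); without any other library 0 genes passed. Bambi, a decoy receptor of the TGF-beta pathway, stood at 20.3 ± 6.86 and 54.2 ± 6.38 CPM (1.42 ± 0.25, adjusted p = 0.0899). Cholesterol synthesis had its highest median here, 0.58, with 17 of 20 positive (camera adjusted p = 0.000246, and 0.532 with an estimated correlation). None passed over all genes, and Idi1 (1.08 ± 0.24, adjusted p = 0.108), Sc4mol, now named Msmo1 (1.18 ± 0.27, 0.112), and Cyp51 (0.89 ± 0.27, 0.116) were among those that passed when adjusted over the list alone. NK genes (median 1.26), proliferation (0.63), interferon (0.54) and matrix remodelling (1.20) were called higher. MHC class II (−1.62, 7 passing over the list alone), monocyte genes (−1.73), colony-stimulating factors (−0.64) and the 6 lists of non-tumour tissue, from −2.29 for skeletal muscle to −3.47 for secretory genes, were called lower. With an estimated correlation 0 of these lists held, with adjusted p from 0.532 to 0.687. When IgG replicate 3 was left out, the medians were 0.082 for proliferation, 0.097 for interferon, 0.66 for matrix, −1.01 for colony-stimulating factor, −1.14 for luminal, −0.73 for basal, −2.08 for secretory, −1.52 for smooth muscle, −0.63 for skeletal muscle and −1.24 for fat genes. Without IgG replicate 3 the calls of skeletal muscle, basal, secretory, fat, proliferation and interferon genes ended, without IgG replicate 2 those of monocyte and fat genes and of colony-stimulating factors, without IgG replicate 1 or the combination's replicate 3 the last of these, and without the combination's replicate 2 that and fat genes. Monocyte genes had a median of 0.061 without IgG replicate 2. Without IgG replicate 3, 1 list, macrophages, held with an estimated correlation (0.0261). Androgen-responsive genes (−0.26, adjusted p = 0.066) and uptake and efflux genes (−0.15, 0.423) were not called, with medians of −0.19 and −0.047 when IgG replicate 3 was left out. That fit added calls of T cell (−0.58, 0.0159), B cell (−0.90, 0.0474) and inflammatory genes (−0.80, 0.0224) as lower, with adjusted p from 0.602 to 0.634 with an estimated correlation.

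The effect of Lupron averaged over tumours with and without the antibody had no gene that passed in edgeR: the lowest adjusted p was 0.525, with 1366 at an unadjusted p under 0.05 and 12 called by DESeq2, 11 of them lower. Without IgG replicate 1, 2 passed. The lower genes with the smallest p were Stc1 (−1.01 ± 0.21), F13a1 (−1.64 ± 0.35), Cav1 (−0.98 ± 0.21) and Foxo3 (−0.83 ± 0.18), the last at 34.4 ± 6.80, 25.0 ± 3.61, 16.8 ± 0.868 and 16.1 ± 5.17 CPM with IgG, anti-CSF1, Lupron and both. NK genes (0.69, 13 of 14 positive), interferon genes (0.29, 21 of 22), T cell genes (0.47), MHC class II genes (0.49), proliferation (0.20) and cholesterol synthesis (0.19) were called higher, and luminal (−0.84), basal (−1.43), smooth muscle (−0.98), endothelial (−0.28) and immediate early genes (−0.36) lower, with adjusted p from 0.659 to 0.726 with an estimated correlation. The call of T cell genes held in all 12 fits that left out a library. Removing IgG replicate 3 ended the calls of NK, luminal, basal, smooth muscle, proliferation and interferon genes, with medians then of 0.41, −0.24, −0.30, −0.24, −0.072 and 0.076, and the T cell and MHC class II medians were then 0.23 and 0.31. Removing IgG replicate 1 ended those of endothelial and immediate early genes, IgG replicate 2 that of cholesterol synthesis, anti-CSF1 replicate 2 those of MHC class II and cholesterol synthesis, anti-CSF1 replicate 3 that of endothelial genes, and Lupron replicate 1 those of smooth muscle and cholesterol synthesis genes. Macrophage (−0.17, adjusted p = 0.35), androgen-responsive (−0.18, 0.13) and steroid synthesis genes (−0.51, 0.13) were not called. Leaving out IgG replicate 3 took these medians to −0.25, −0.12 and −0.098. The macrophage list was then called lower (0.0209), as were fibroblast (−0.26, 0.0449) and hypoxia genes (−0.38, 0.0392), and fat genes higher (0.041, median 1.03 at the counting limit), each with an adjusted p of 0.773 with an estimated correlation.

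Whether the antibody acted differently with Lupron than without it was tested as an interaction. Csf1r differed by −0.16 ± 0.59 (adjusted p = 0.954), the macrophage list by a median of −0.10 (camera adjusted p = 0.349) and cholesterol synthesis by 0.03 (0.945). Among macrophage genes, Cd163 stood at 22.6 ± 15.1 and 3.93 ± 0.836 CPM without and with the antibody, and at 6.63 ± 1.16 and 6.63 ± 0.518 in Lupron tumours (2.53 ± 0.66, adjusted p = 0.488). No gene passed in edgeR: the lowest adjusted p was 0.488, with 1021 at an unadjusted p under 0.05 and 188 called by DESeq2, 184 of them higher. Without IgG replicate 1, 5 passed. Of the 31 lists, 13 were called with the preset correlation and 0 with an estimated one. When IgG replicate 3 was left out, 9 of the 13 were still called; T cell, proliferation, inflammatory and matrix genes were not, and MHC class II genes were not without anti-CSF1 replicate 1. That fit without IgG replicate 3 added calls of monocyte (0.31, 0.037), fibroblast (0.29, 0.037) and interferon genes (0.42, 0.0104) as higher, with adjusted p from 0.683 to 0.698 with an estimated correlation, and put the macrophage median at 0.17 (0.905). Fat genes had the largest median among the called lists (13.65 with absent genes at the counting limit, and 11.20 without IgG replicate 3) and hypoxia genes the lowest (−1.12, and −0.72 without it).

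On mouse genome build GRCm38 (mm10), GENCODE M21 places Csf1r on chromosome 18 at 61100598 to 61132149, Csf1 on 3 at 107741048 to 107760469, Apoe on 7 at 19696109 to 19699188, and Fcna on 2 at 25624666 to 25628030. Gzmb lies on 14 at 56258838 to 56262260, Gzmc on 14 at 56231441 to 56234656, Gzmd on 14 at 56129556 to 56132608, Gzme on 14 at 56117626 to 56120625, Gzmf on 14 at 56205263 to 56211417 and Gzmg on 14 at 56156582 to 56159579. Il33 lies on 19 at 29925114 to 29960718, Abca1 on 4 at 53030787 to 53159895 and Erg on 16 at 95359169 to 95586593. Of the 256 genes selected for naming, 254 matched a single gene of that symbol, 6 overlap another coding gene on the same strand and 25 one on the other strand, Csf1r among the latter; whether counting was strand-specific is not given in the sources used here.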

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

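The tests of IgG replicate 3 described here were chosen after its values were seen; the splits of the libraries were planned, apart from reading them by the count at an unadjusted p. The difference between the antibody's effect with Lupron and without it was called for 13 of 31 gene lists (set test with preset correlation, adjusted p given for each), and for 0 with an estimated correlation, where the adjusted p ran from 0.287 to 0.721. Of these, 6 were lists of non-tumour tissue, each lower with the antibody than with IgG and less so, or higher, under Lupron: fat (3.51e-13, median difference 13.65 with absent genes at the counting limit), luminal epithelium (5.65e-09, 2.2), prostate secretion (6.81e-07, 3.38), smooth muscle (2.63e-05, 2.85), skeletal muscle (0.000681, 3.00) and basal epithelium (0.00174, 3.31). Androgen-responsive genes went the same way (0.00625, 0.47). The other lists went the opposite way: hypoxia (6.03e-05, −1.12), proliferation (0.000236, −0.49), T cells (0.000817, −0.93), MHC class II (0.00138, −1.02), inflammatory cytokines (0.00625, −0.68) and matrix remodelling (0.00642, −0.73). The MHC class II level (mean log2 of CPM plus 1) was 5.31 ± 0.68 with IgG and 3.98 ± 0.66 with anti-CSF1, and 6.26 ± 0.036 with Lupron and 4.08 ± 0.28 with the combination. Without IgG replicate 3, the calls of T cell, proliferation, inflammatory and matrix genes ended, and 9 of the 13 stayed, each with a median nearer 0: 1.20 for luminal, 2.73 for secretory, 1.37 for smooth muscle, 1.51 for skeletal muscle, 0.79 for basal, 0.33 for androgen-responsive, −0.72 for hypoxia and −0.67 for MHC class II genes, and 11.20 for fat genes at the counting limit. The medians of the 4 that ended were −0.56 for T cells, 0.036 for proliferation, −0.15 for cytokines and −0.40 for matrix. Without anti-CSF1 replicate 1 the call of MHC class II ended.

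The pattern weighed is that IgG replicate 3 stands apart from the other 11 libraries. Degraded RNA is argued against by the labels: 4 other libraries had a RNA integrity number at or below its value of 8.9, and 3 of them had median rank correlations with the other libraries from 0.969 to 0.975, against 0.759 for IgG replicate 3. The exception is IgG replicate 2, with the lowest integrity number of 8.2 and the next lowest correlation, 0.935. Non-tumour tissue in the sample is a candidate explanation: the 6 lists named above were highest in this library, and its proliferation level was lowest at 2.74. Myh11, Krt5 and Msmb stood at 5981, 485 and 1207 CPM in it, against at most 1021, 16.9 and 89.7 in any other library. Other lists of non-tumour cells went the other way. Fibroblast (6.12) and endothelial genes (4.07) were lowest in this library, and seminal vesicle genes (5.11) ranked 11 of 12. Tumour cells may themselves express part of the luminal and androgen-responsive genes, so the share of normal tissue was not estimated. Tumour size and dissection are not given in the sources used here, so an effect of treatment on how much normal tissue came with a tumour stays open.

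Other splits of the libraries into groups of the same sizes were run for every comparison. For the averaged antibody effect, 1 of 100 splits, the real one, called as many as its 282 genes, and the highest other called 153. That other split differed from the real one only by an exchange of IgG replicate 3 and anti-CSF1 replicate 1, with the sides renamed. It therefore still held part of the antibody's effect. The share of 1 in 100 argues against chance for the count over all libraries. The count changed with the library left out, and splits of those fits were not run. The averaged Lupron effect and the interaction called 0 genes, which every split reaches (100 of 100 each, with 67 and 0 as the highest other), so these counts say nothing about chance. At an unadjusted p under 0.05 the antibody had 2873 genes, reached by 3 of 100 splits (highest other 3351), Lupron 1366, reached by 15 of 100 (3943), and the interaction 1021, reached by 30 of 100 (3225), so by that count chance is not excluded for the last 2. The split with 67 genes set IgG replicates 2 and 3 and Lupron replicate 2, with anti-CSF1 replicate 2 and the combination's replicates 1 and 2, against the other 6 libraries, which may reflect a structure of the samples other than Lupron; what these libraries share was not tested. For comparisons of 3 with 3, the 10 splits are too few for a share under 0.1. Anti-CSF1 against IgG called 1 gene and the combination against IgG 1, each in 1 of 10 splits, with 0 as the highest other. Lupron against IgG, the combination against Lupron and the combination against anti-CSF1 called 0 in 10 of 10 splits (highest other 0). At an unadjusted p under 0.05, Lupron against IgG had 2478 genes, reached by 2 of 10 splits (highest other 3969). The combination against anti-CSF1 had 294, reached by 5 of 10 (1452). Only the real split reached the 3446 genes of anti-CSF1 against IgG (highest other 2661). The same held for the 3922 of the combination against IgG (2162) and the 642 of the combination against Lupron (617).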

How the results depend on the processing

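Leaving out IgG replicate 3 with Lupron replicate 2, the tissue covariate and removing seminal vesicle genes were chosen after seeing the data, and the other alternatives before. Counts of called genes depended on the libraries and on the test. Anti-CSF1 against IgG had 1 gene called, and 2 with RLE scaling, upper-quartile scaling, the stricter filter, the RNA integrity covariate or seminal vesicle genes removed. It had 0 with its groups alone or with the tissue covariate, 141 without IgG replicate 3 and Lupron replicate 2, 1841 with DESeq2, and 0 to 2611 with 1 library left out. The combination against IgG had 1, and 3 with RLE scaling, no filter, the stricter filter or seminal vesicle genes removed, 4 with upper-quartile scaling, 0 with its groups alone or the tissue covariate, 198 without both libraries, 2076 with DESeq2, and 0 to 2213 with 1 library left out. The combination against Lupron had 0, and 5 with RLE scaling or the stricter filter, 7 with upper-quartile scaling, 2 without a filter, 204 with its groups alone, 141 without both libraries, 52 with the tissue covariate, 235 with DESeq2, and 0 to 210 with 1 library left out. Lupron against IgG had 0, 404 with DESeq2 and 0 to 653 with 1 library left out; the combination against anti-CSF1 had 0, 6 with DESeq2 and 0 in each fit with 1 library left out. The averaged antibody effect had 282, and 235 to 381 under the alternatives other than DESeq2 (1425), the block and leaving out 1 library (65 to 1577). The averaged Lupron effect had 0, 12 with DESeq2 and 0 to 2 with 1 library left out, and the interaction 0, 188 with DESeq2 and 0 to 5. The upper ends 653, 2611, 2213 and 1577 came without IgG replicate 1. That fit leaves in the IgG group the 2 libraries highest for the 6 lists of non-tumour tissue. The cause of these differences in counts was not tested.

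With the replicate number as a block, the counts were 0 for both comparisons with IgG that had 1, and 151 for the averaged antibody effect, 146 of them among the 282. Expression after removal of group means correlated above 0.1 in 7 of 18 same-numbered pairs (−0.32 to 0.34), and 4 of 12 libraries correlated best with one of their own number, so no pairing was assumed.

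The macrophage list kept its direction and its preset-correlation call with every library left out, at −2.35 to −1.62 for anti-CSF1 against IgG and −2.36 to −1.91 for the combination against Lupron. With an estimated correlation the former, at −1.98, was not called (adjusted p = 0.413). Androgen-responsive genes in Lupron against IgG, at −0.41, were not called with an estimated correlation (0.52) or fry (0.309), stood at −0.29 with the tissue covariate (0.336), and ran from −0.50 to −0.22 with 1 library left out. Cholesterol synthesis in the combination against Lupron, at 0.33, was not called with an estimated correlation (0.583) or fry (0.481), stood at 0.17 without both libraries (0.0943), and ran from 0.19 to 0.47 with 1 library left out. For these 3 results the cause was not tested.

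Among lists called in a comparison, several changed the sign of their median or the direction of the test; lists that were not called are left out here. Without IgG replicate 3 and Lupron replicate 2, interferon genes stood at −0.16 for anti-CSF1 against IgG and −0.044 for the averaged antibody effect, and NK genes at −0.074 for Lupron against IgG. With the tissue covariate, anti-CSF1 against IgG had −0.69 for proliferation and −0.47 for interferon; Lupron against IgG had 0.015 for skeletal muscle, 0.31 for secretion, −0.66 for proliferation, −0.25 for interferon and −0.026 for matrix genes; and the combination against IgG had 0.24 for fat, −0.47 for secretion, −0.42 for proliferation and −0.047 for interferon. With it the averaged antibody effect had −0.20 for proliferation and −0.13 for interferon, the averaged Lupron effect −0.19 for proliferation, and the interaction 0.88 for proliferation, 0.20 for inflammatory and 0.14 for matrix genes. With 1 library left out, sign changes of called lists lay in the ranges −0.16 to 0.85 (interferon) for anti-CSF1 against IgG, −0.11 to 0.87 (proliferation) and −0.14 to 0.92 (interferon) for Lupron against IgG, −2.30 to 0.061 (monocytes, without IgG replicate 2) for the combination against IgG, −0.072 to 0.42 (proliferation) for the averaged Lupron effect and −0.88 to 0.036 (proliferation) for the interaction; apart from monocytes they came without IgG replicate 3. The cause was not tested. The tissue covariate was not applied to the luminal, basal and smooth muscle lists, which define it.

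Over all settings and named genes, 14074 gene values kept their direction and side of the threshold, 580 were newly called and 206 lost a call. A further 131 changed sign without being called in either fit, and 0 called genes reversed. Of list values 1574 were the same, 339 lost a call and 26 reversed. No scaling moved the median of all genes by over 0.1 on the log2 scale. With 20584363 to 29965355 counts per library, a group without counts of a gene allows up to 0.0383 CPM with IgG. In simulated data 4.48% of genes changed 2-fold and 80.3% of those changed 8-fold were recovered for anti-CSF1 against IgG. The simulation held no library that stands apart and no correlation between genes, so these shares need not hold for the real libraries.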

Other observations

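The tests of granzymes and cholesterol synthesis described here were chosen after the results were seen. The granzyme genes Gzmc to Gzmg rose with the antibody, and Gzmb and Gzma did not pass, in tumours where macrophage, MHC class II and Cd4 transcripts fell. Which granzymes passed depended on the library left out: Gzmb passed in some of those fits, and each of Gzmc to Gzmg lost its call in some. Cholesterol synthesis genes had positive medians in each comparison of antibody with no antibody, 0.31 without Lupron and 0.33 with it, and were called in neither with an estimated correlation (adjusted p = 0.594 and 0.583).

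The 5 granzyme genes Gzmc to Gzmg rose by 3.40 to 8.32 on the log2 scale. Reads of 1 gene shared between Gzmc and Gzmd are argued against, since the ratio of Gzmd to Gzmc counts differed by a factor of 9.96 between antibody libraries. Sharing among Gzmd, Gzme, Gzmf and Gzmg stays open, since the smallest factor among their 6 pairs was 1.49, and these 4 could represent fewer genes. The median of 7 NK lineage genes was 0.94, and the highest of them plus 2 standard errors reached 3.02. The smallest granzyme change, 3.40 for Gzmc, lies above this, but not once 2 of its own standard errors are taken off. For Gzmc the test therefore cannot decide whether more NK cells are the whole cause. Gzmd to Gzmg stay above 3.02 with theirs taken off, which argues against it for these genes. This takes the 7 genes to follow NK cell number, which was not tested. A change in the state of killer cells, or in T cells that carry these genes, may contribute and was not tested.

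Cholesterol synthesis genes were called higher in the combination than in Lupron tumours with the preset correlation (median 0.33), but not with an estimated correlation (adjusted p = 0.583), with fry (0.481) or without Lupron replicate 2 (0.073), and 0 of 20 genes passed singly. Lupron replicate 2 alone may account for part of this: without it the median was 0.19, so this stays open. A larger tumour share of the RNA could raise them too, as the cholesterol synthesis level minus the proliferation level rose by 0.0923 with a pooled SD of 0.125 between libraries. An effect of the antibody treatment stays open too and was not tested apart from these, and bulk RNA does not say which cells carried the transcripts.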
